A study of Homo sapiens with 6 samples.

How the data were processed

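RNA was measured in 6 libraries of the EndoC-BH5 line, 3 of the vehicle group and 3 of the cytokine group, grouped by the treatment label of each sample. Total RNA was extracted with a Nucleospin miRNA kit and libraries were made with the NEBNext Ultra II Directional kit, per the labels' protocols. Cytokine doses and exposure time were not given in the sources used here. The tools cutadapt 2.10, STAR 2.7.5a, HTSeq 0.12.4, FastQC 0.11.9, Picard 2.23.2 and MultiQC 1.9 and the build GRCh38 were named without roles or parameters, per the submitters' processing notes. The annotation release and the strand setting of the counting were not given in the sources used here.

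The authors deposited a table of 60611 genes with an estimated count per gene and library that was not normalised and need not be whole, per the values and the file headers. Of the genes above 0, 67.3% to 73.5% lay within 0.005 of a whole number in a library, and the origin of the fractions was not given in the sources used here. The columns whose names carry NT were taken as the vehicle libraries, since the other 3 columns carry the cytokine name and the replicate numbers are shared with the sample titles. The authors also deposited their mean count per group, a log2 fold change, a mean log2 CPM, an F score and a p-value with its FDR for each gene, per the file headers, with no tool named. From the authors' deposited table, only the fold changes and FDR values were used, to count calls beside the refit. The length column equalled gene end minus start in 72.6% of the matched genes and was not used. Of all identifiers, 35257 had a symbol in the table and 60462 were matched to a gene names table. Coordinates were taken from GENCODE 29 on GRCh38, which held 58352 of the identifiers.

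Estimated counts were rounded to whole numbers before testing, although the planned design named counts as deposited. Genes were filtered with filterByExpr, which left 17863 genes, and scaled with TMM, with factors of 1.08, 1.06 and 1.08 in vehicle replicates 1, 2 and 3 and 0.931, 0.932 and 0.934 in cytokine replicates 1, 2 and 3. The test was edgeR 4.0.16 (R 4.3.3), with a robust quasi-likelihood fit on group alone and Benjamini-Hochberg adjustment at 0.05. The SE of a log2 fold change was its size divided by the square root of F. Total counts ranged from 5871481 to 16175364, so levels near 1 CPM rested on few counts, most of all in vehicle replicate 1. For genes with 0 vehicle counts, fold bounds used a floor of 3 counts over the group, and for 1 to 3 counts a ratio with a 95% counting interval.

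The comparison was cytokine against vehicle. Lists of genes, 33 in number, were fixed before the data were examined, and 31 with at least 5 tested members were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and a prior count of 2, two-sided, adjusted over the 31 lists. An estimated correlation and fry were computed beside it. An exact permutation test was used for the contrast of immunoproteasome and constitutive proteasome genes. The rule for named genes took 15 genes in advance, among them INS, IAPP, PDX1, MAFA, NKX6-1, IRF1, CD274, CXCL10, HLA-B, HLA-C, B2M, NOS2 and MKI67. It added the 6 genes with the largest rise and the 6 with the largest fall past the test with at least 5 CPM in the higher group, no overlap between groups and a gene symbol. It also added up to 2 higher and 2 lower members of each list by the size of change, with at least 1 CPM in the higher group, or the 2 members with the highest level where fewer than 2 passed. Some genes that the rule named are not reported here.

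The scripts were tested on simulated data drawn for the 17863 genes of this comparison with 200 changed genes. Of those changed by 0.25, 0.5, 1 and 2 on the log2 scale, 38%, 90%, 98% and 100% were recovered, and 4 of 167 calls were false. The changed genes were drawn above a vehicle mean of 2 CPM and changed in random directions. In the real comparison 57.1% of tested genes passed, so these rates do not cover errors of scaling or genes at lower levels. Replicates of a group were compared by a chi-square of their counts over genes, which gave 1.38 to 2.47 per gene, so no pair of libraries was counted as 1.

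Alternatives were DESeq2 size factors in edgeR, scaling by library size alone, DESeq2 1.42.0 on genes above 0 with its own filter, no filter on low counts, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, each library left out in turn, an adjusted p of 0.01, and glmTreat against a fold of 1.5. Counting INS together with INS-IGF2 and DESeq2 on the genes kept by the count filter were added after the data were seen. Genes below the filter were not tested. A gene nearly silent in vehicle was thus tested only if it rose, so shares of tested members can overstate the rise of a whole list.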

Results

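RNA from EndoC-BH5, a human pancreatic beta-cell line, was sequenced in 6 libraries, 3 from cultures given vehicle and 3 from cultures given interferon gamma together with interleukin 1 beta, both of which are inflammatory cytokines. The total count was 5871481, 10257431 and 15894082 in vehicle replicates 1, 2 and 3, and 16175364, 13689972 and 14805245 in cytokine replicates 1, 2 and 3. The common biological coefficient of variation was 3.46%. The labels do not say whether the 3 batches of a group were separate cultures, so p-values measure the spread between these samples, which may be technical. The comparison asked how the transcriptome of the line differed after exposure to the cytokine pair. Levels below are CPM, counts scaled to a common library size after TMM scaling, given as mean ± SD over n = 3 libraries, and changes are log2 fold changes of cytokine over vehicle with their standard error (SE).

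Most tested genes of the interferon response and of antigen presentation rose with cytokines. The mRNA of CXCL10, a chemokine that attracts T cells, went from 1 count over the 3 vehicle libraries to 4442 ± 61.7 CPM, and CXCL9 went from 0 counts to 2627 ± 76.3 CPM. The transcription factor IRF1 rose 61.3-fold. Genes for insulin production and glucose sensing mostly fell, as did cell cycle genes, while INS itself differed by little and IAPP, which encodes the islet amyloid peptide co-secreted with insulin, rose 2.06-fold to 8238 ± 208 CPM. Of the tested genes named below, the libraries of both groups overlapped in INS, INS-IGF2, IFNGR1, PSMB5, PSMB7, RFXANK, RFXAP, CREB3L2, MT-ND3 and CPA1. They did not overlap in the others. IFNGR1, IFNGR2, RFXANK, PCSK1N, CREB3L2, C4A, INS-IGF2, ART3, IDO1, GBP3 and HLA-DRA lay outside the rule for named genes and were chosen after their values were seen. So were PSMB5, PSMB6, PSMB7, IL6 and CCL2.

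Of 17863 genes tested, 5061 were higher and 5140 lower with cytokines, and 7662 did not pass the edgeR quasi-likelihood test. Most called changes were small, since 6194 called genes changed by less than 1.5-fold. At least 2-fold changes were found in 1065 higher and 765 lower genes, and at least 8-fold changes in 252 higher and 13 lower genes. Higher genes made up 49.6% of all calls with TMM scaling and 25.3% when libraries were scaled by size alone, which shifted the median gene by -0.20 on the log2 scale. The libraries of both groups did not overlap in 10893 tested genes, or 61.0%, where chance gives 10%. In the authors' deposited table, 5009 genes were higher and 4792 lower, and 9287 of the tested genes were called there and in the refit with the same sign, with 0 called in opposite directions.

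The 6 genes with the largest rise by the fixed rule were CXCL9, CXCL10, GBP1, BST2, ICAM1 and GBP5. With few or no vehicle counts their order depends on the fit, and the place of GBP5 above GBP3, which was 4744-fold higher with a 95% counting interval from 1313 to 39175, was not established. CXCL9 lies on chromosome 4 at 76001275 to 76007488 and CXCL10 at 76021117 to 76023497, both on the minus strand in GRCh38. ART3, on the plus strand at 76011184 to 76112802, spans CXCL10, and with the counting strand not stated the values of overlapping genes on opposite strands are uncertain. With 0 vehicle counts, CXCL9 was at least 30002-fold higher, the interferon-induced GTPase GBP1 at least 7729-fold, the antiviral membrane protein gene BST2 at least 3409-fold and GBP5 at least 521-fold, against a floor of 3 counts over the group. CXCL10 was 152190-fold higher with a 95% counting interval from 27314 to 6011200. ICAM1, which encodes an adhesion molecule bound by leukocytes, was 9015-fold higher with an interval from 1618 to 356090, and reached 263 ± 6.80 CPM. These intervals and floors cover counting error only.

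Among 29 tested members of the interferon gamma signalling list, 26 rose, PTPN6 fell and 2 did not pass the test (camera, adjusted p = 1.6e-19). The 2 were the receptor genes IFNGR1 at 49.3 and 48.8 CPM and IFNGR2 at 63.1 and 67.0 CPM in vehicle and cytokine libraries. The PTPN6 call (edgeR, adjusted p = 0.036) was lost with DESeq2 with or without the count filter and in edgeR with no count filter (0.111). It was also lost without vehicle replicate 1 (0.107) or 3 (0.107) and without cytokine replicate 1 (0.150) or 2 (0.145). Its adjusted p ranged from 2.9e-05 to 0.246 over 13 alternatives. IRF1, a transcription factor of the interferon response, went from 20.1 ± 0.767 to 1229 ± 28.4 CPM, a log2 change of 5.94 with SE 0.0543 (edgeR, adjusted p = 6.8e-34). All 40 tested members of the antiviral interferon-stimulated list rose, each at least 2-fold (camera, adjusted p = 1.2e-25). SAMD9L had 0 vehicle counts and was at least 204-fold higher.

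**Figure D1:**
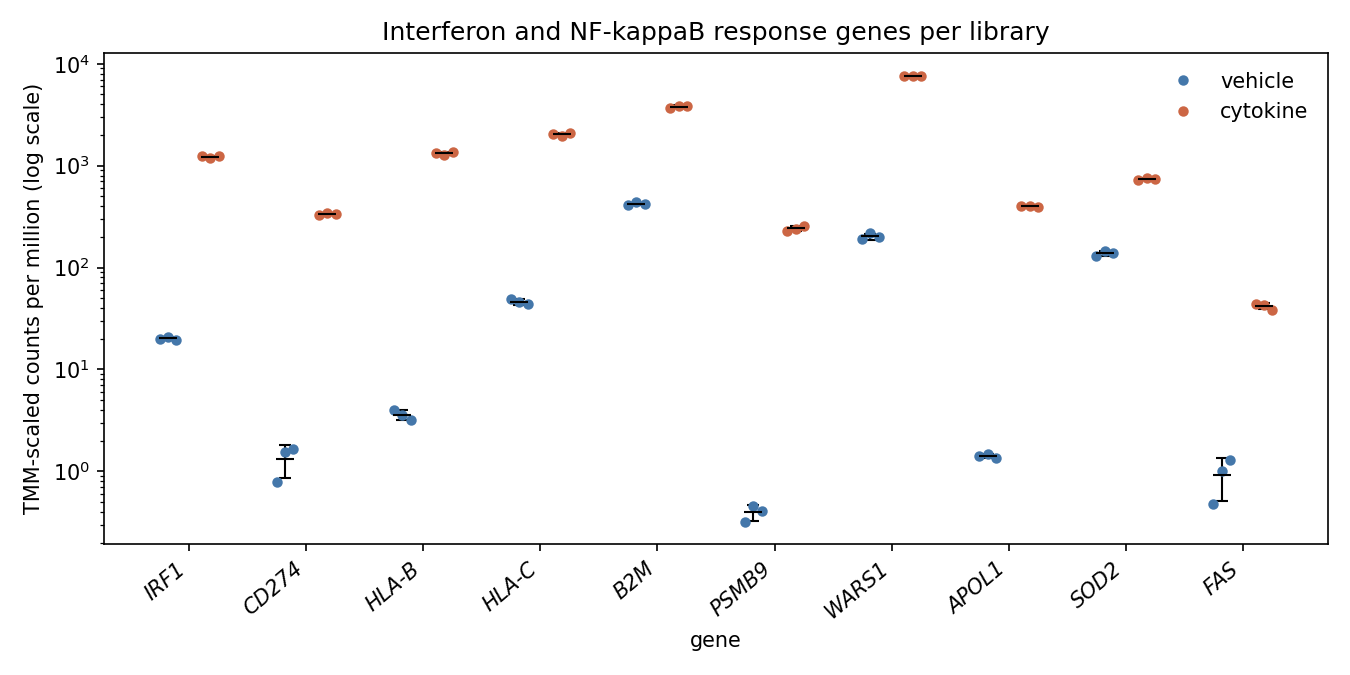
TMM-scaled CPM on a log axis for 10 response genes in the 6 libraries, with a point for each library, a horizontal mark at the group mean and bars of 1 SD (n = 3). For each gene the cytokine points lie above the vehicle points, from 1.33 to 336 CPM on average for CD274 and from 202 to 7615 CPM for WARS1.

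All 22 tested members of the MHC class I presentation list rose, 20 of them at least 2-fold (camera, adjusted p = 5.7e-19). HLA-B went from 3.59 ± 0.376 to 1319 ± 42.7 CPM and HLA-C from 46.2 ± 2.96 to 2024 ± 84.2 CPM, with log2 changes of 8.56 (SE 0.0709) and 5.47 (SE 0.0530). Values of single HLA genes are uncertain because near-identical family members can share reads. B2M, the light chain of class I molecules, rose 8.96-fold to 3796 ± 125 CPM, and PSMB9, an immunoproteasome subunit, went from 0.395 to 243 CPM. The 20S list of constitutive proteasome subunits includes many that the immunoproteasome shares. Of its 14 genes, 12 rose, with PSMA6 the most at a log2 change of 1.75 (camera, adjusted p = 5.0e-05). PSMB5 and PSMB7 did not pass, with log2 changes of -0.081 and -0.056, and PSMB6 rose by 0.21. That list call was lost with an estimated correlation (camera, adjusted p = 0.20). The 5 genes of the immunoproteasome and its activator had a median log2 change of 4.70 against 0.64 for the 14 genes of the 20S list. The difference of their mean log2 levels was -2.80 ± 0.0343 in vehicle and 1.38 ± 0.0221 in cytokine libraries, a change of 4.18 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows).

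Of 18 listed MHC class II genes, 9 were tested, of which 7 rose, RFXAP fell and RFXANK did not pass (camera, adjusted p = 0.00037). The call was lost with an estimated correlation (camera, adjusted p = 0.15). The RFXAP call (edgeR, adjusted p = 0.021) was lost with DESeq2 with or without the count filter, without vehicle replicate 3 (0.242) and without cytokine replicate 3 (0.197), and its adjusted p ranged from 0.00018 to 0.242 over 13 alternatives. CTSS, a lysosomal protease that processes antigen, went from 0.404 to 118 CPM, and CIITA, the class II transactivator, from 0.123 to 20.5 CPM. The untested members had at most 7 counts in any library. Among them, the class II chain gene HLA-DRA had 0 counts in each vehicle library and 2, 1 and 1 in the cytokine libraries.

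Of 39 listed targets of NF-kappaB and interleukin 1, 30 were tested, of which 27 rose and 3 did not pass (camera, adjusted p = 4.8e-12). Apart from NOS2, the untested targets, IL6 and CCL2 among them, had at most 7 counts in any library. CFB, which encodes complement factor B, went from 3 counts over the vehicle libraries to 23.5 CPM, and SOD2, the mitochondrial superoxide dismutase, rose 5.37-fold. Of 11 genes of the interleukin 1 receptor pathway, 5 rose, 3 fell and 3 did not pass, and with scaling by library size alone 2 rose and 5 fell (camera with TMM, adjusted p = 0.43). The adaptor MYD88 rose 2.21-fold, while IL1RAP and SIGIRR fell by 0.59 and 0.53 on the log2 scale.

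Of 41 listed chemokine and cytokine genes, 24 were tested, of which 20 rose and 4 did not pass (camera, adjusted p = 6.3e-13). The untested ones had at most 5 counts in any library. Of 24 listed T-cell checkpoint and costimulation genes, 13 were tested, of which 10 rose and 3 did not pass (camera, adjusted p = 6.4e-07). CD274, which encodes the inhibitory ligand PD-L1, went from 1.33 ± 0.467 to 336 ± 5.89 CPM, a log2 change of 7.84 with SE 0.0899 (edgeR, adjusted p = 1.4e-31). Complement genes rose in 9 of 12, C5 fell and 2 did not pass (camera, adjusted p = 0.00037), and the call was lost with an estimated correlation (camera, adjusted p = 0.0505). C4B rose from 12.5 to 992 CPM, a value that is uncertain because its near-identical neighbour C4A can share its reads. All 5 tested APOL genes rose, APOL1 from 1.41 to 398 CPM (camera, adjusted p = 1.8e-06).

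In the kynurenine and tryptophan list, 5 of 6 genes fell and WARS1, the tryptophanyl-tRNA synthetase, rose 37.7-fold (camera, adjusted p = 0.13). Its median change was -0.84 and its mean 0.18 on the log2 scale, so these differ in sign, and fry gave the upward direction. AFMID and HAAO, enzymes of tryptophan breakdown, fell by 1.16 and 1.12 on the log2 scale. IDO1 was not tested, with at most 5 counts in any library.

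Of 25 tested genes for insulin production and glucose sensing, 20 fell, 4 rose and PCSK1N did not pass, and 20 fell and 2 rose with scaling by library size alone (camera with TMM, adjusted p = 3.5e-05). G6PC2, a glucose-6-phosphatase subunit of islets, went from 42.0 ± 2.46 to 6.63 ± 0.193 CPM, a log2 change of -2.67 with SE 0.0854 (edgeR, adjusted p = 8.2e-21). ENTPD3 fell by 1.73 on the log2 scale and SLC30A8, the zinc transporter of insulin granules, by 1.11. IAPP went from 3997 ± 193 to 8238 ± 208 CPM, and PCSK1, a prohormone convertase, rose 1.67-fold.

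INS, on the minus strand of chromosome 11 at 2159779 to 2161341 in GRCh38, went from 4011 ± 163 to 3641 ± 291 CPM, a log2 change of -0.14 with SE 0.0446 (edgeR, adjusted p = 0.0094). The libraries overlapped, since cytokine replicate 3 had 3948 CPM and vehicle replicate 1 had 3890 CPM. The call was lost with DESeq2 and its own filter (adjusted p = 0.246), though not with DESeq2 and the count filter (adjusted p = 0.0281). It was also lost without vehicle replicate 2 (log2 change -0.094, edgeR, adjusted p = 0.0937) and without cytokine replicate 1 (log2 change -0.075, edgeR, adjusted p = 0.193). Over 14 alternatives the log2 change ranged from -0.34 with scaling by library size alone to -0.075, and adjusted p from 3.4e-07 to 0.246. The INS value is uncertain because INS-IGF2 overlaps it on the same strand and the counting of shared reads was not described. Counted together, both had 7957 ± 303 and 7248 ± 566 CPM, a log2 change of -0.13 (edgeR, adjusted p = 0.0096).

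Of 24 beta-cell transcription factor genes, 12 fell, 8 rose and 4 did not pass, and 15 fell and 3 rose with scaling by library size alone (camera with TMM, adjusted p = 0.14). PDX1, a regulator of INS, went from 222 ± 19.1 to 153 ± 15.1 CPM, a log2 change of -0.53 with SE 0.0659 (edgeR, adjusted p = 1.7e-06). MAFA went from 5.16 ± 1.04 to 1.46 ± 0.131 CPM, a log2 change of -1.89 with SE 0.195 (edgeR, adjusted p = 2.6e-09). NKX6-1 went from 161 ± 3.92 to 174 ± 5.58 CPM, a log2 change of 0.12 (edgeR, adjusted p = 0.027) that turned to -0.087 when libraries were scaled by size alone (edgeR, adjusted p = 0.076). Its call was also lost with no count filter (edgeR, adjusted p = 0.0520), without vehicle replicate 3 (edgeR, adjusted p = 0.132) and without cytokine replicate 1 (edgeR, adjusted p = 0.103), and ranged from 0.0059 to 0.132 over 13 alternatives.

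**Figure D2:**
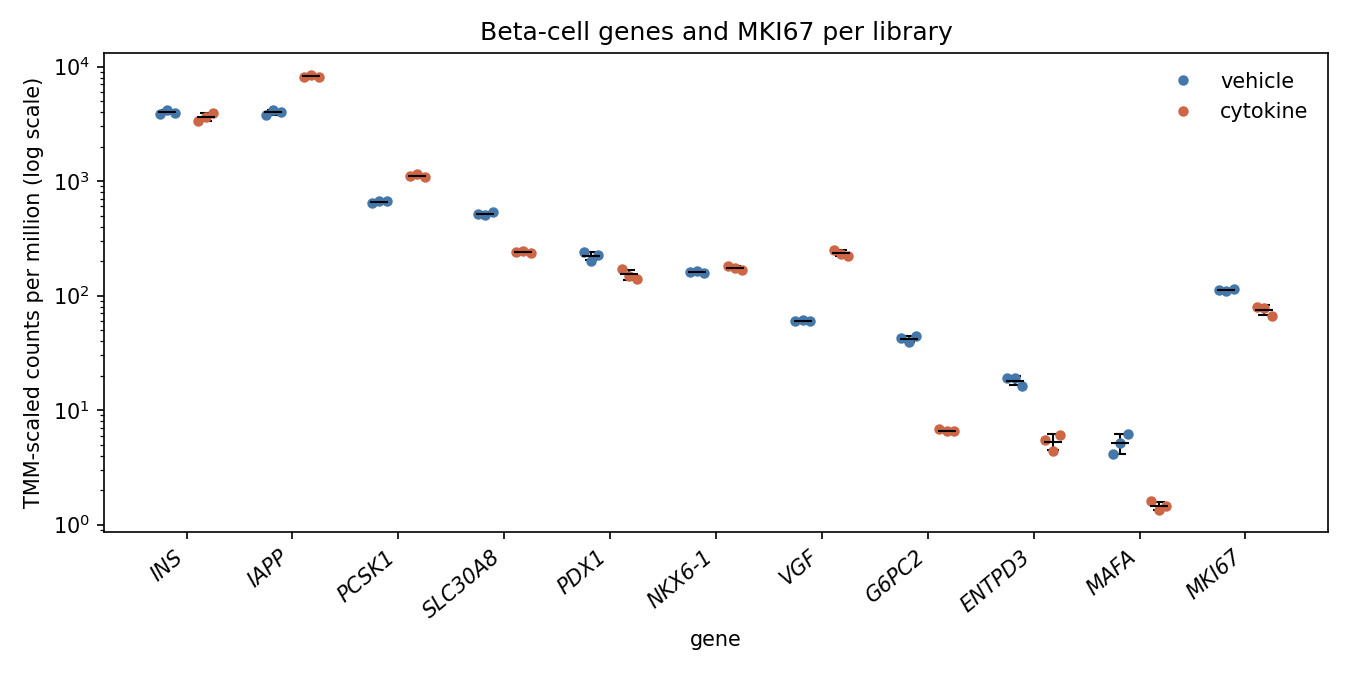
TMM-scaled CPM on a log axis for 10 beta-cell genes and MKI67 in the 6 libraries, with a point for each library, a horizontal mark at the group mean and bars of 1 SD (n = 3). INS points overlap between groups, IAPP lies higher with cytokines at 8238 against 3997 CPM, and G6PC2 lies lower at 6.63 against 42.0 CPM. The NKX6-1 difference turns in direction when libraries are scaled by size alone.

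Secretory granule and exocytosis genes rose in 19 of 30, fell in 5 and did not pass in 6 (camera, adjusted p = 0.0016), and with scaling by library size alone 11 rose and 9 fell. The list call was lost with an estimated correlation (camera, adjusted p = 0.11). VGF, a granule neuropeptide precursor, rose 3.88-fold to 234 CPM, and RAB37 fell by 2.08 on the log2 scale. Of 18 islet autoantigen genes, 8 rose, 8 fell and 2 did not pass, and 4 rose and 10 fell with scaling by library size alone (camera with TMM, adjusted p = 0.90). GAD1 went from 2.41 to 6.14 CPM.

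Genes of endoplasmic reticulum (ER) stress rose in 27 of 29, SESN2 fell and CREB3L2 did not pass (camera, adjusted p = 1.3e-08), a call lost with an estimated correlation (camera, adjusted p = 0.20). The SESN2 call (edgeR, adjusted p = 0.027) was lost with DESeq2 with or without the count filter and in edgeR with no count filter (0.0933). It was also lost without vehicle replicate 1 (0.0688) or 2 (0.137) and without cytokine replicate 1 (0.0793) or 2 (0.204). Its adjusted p ranged from 1.3e-06 to 0.204 over 13 alternatives. The stress transcription factor ATF3 rose 5.77-fold and PPP1R15A, a regulator of translation recovery, 3.30-fold. Apoptosis and pyroptosis genes rose in 27 of 33, fell in 3 and did not pass in 3 (camera, adjusted p = 4.3e-09). MLKL, an effector of necroptosis, went from 0.362 to 22.4 CPM, and FAS, a death receptor, from 0.925 to 41.8 CPM. BIK and BCL2 were among those that fell, by 1.32 and 0.47 on the log2 scale, and the BCL2 call was lost with DESeq2 with the count filter (adjusted p = 0.0587) and without it (adjusted p = 0.117, the highest of 13 alternatives, which began at 0.00014).

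Of 24 cell cycle genes, 22 fell and 2 rose (camera, adjusted p = 3.5e-06), a call lost with an estimated correlation (camera, adjusted p = 0.12). MKI67, a proliferation marker, went from 112 ± 1.38 to 74.6 ± 7.47 CPM, a log2 change of -0.58 with SE 0.0567 (edgeR, adjusted p = 7.9e-10). CCND1 and MCM2 rose, to 1.44 and 118 CPM. Cholesterol synthesis genes fell in 13 of 20, rose in 3 and did not pass in 4 (camera, adjusted p = 0.041). That call was lost with an estimated correlation (camera, adjusted p = 0.15). It was also lost with the replicate number as a block (camera, adjusted p = 0.0689), without vehicle replicate 2 (0.0727) or 3 (0.0588) and without cytokine replicate 1 (0.0821), 2 (0.0515) or 3 (0.0528). Over 13 alternatives the adjusted p ranged from 4.9e-05 with fry, which does not compare a list with other genes, to 0.150 with camera and an estimated correlation. STARD4, which carries sterols, rose 1.31-fold.

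Oxidative stress and nitric oxide genes rose in 6 and fell in 12 of 23, with 5 not past the test, and rose in 3 and fell in 15 with scaling by library size alone (camera with TMM, adjusted p = 0.41). Their median change was -0.16, and fry gave the upward direction without passing (adjusted p = 0.326). TXNIP, a thioredoxin inhibitor, fell by 1.86 on the log2 scale. NOS2, the inducible nitric oxide synthase, lay below the count filter with 2, 2 and 4 counts in the vehicle libraries and 13, 9 and 16 in the cytokine libraries, so it was not tested. Metal handling genes rose in 6, fell in 4 and did not pass in 2 of 12, and rose in 4 and fell in 5 with scaling by library size alone (camera with TMM, adjusted p = 0.58). MT2A rose from 0.860 to 18.4 CPM, uncertain because metallothionein genes are near-identical. Of 19 glycolysis genes, 8 rose, 8 fell and 3 did not pass, and 4 rose and 12 fell with scaling by library size alone (camera with TMM, adjusted p = 0.90). Their median was -0.016 and their mean 0.084 on the log2 scale.

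Of 32 nuclear genes of oxidative phosphorylation, 9 rose, 4 fell and 19 did not pass, and 2 rose and 19 fell with scaling by library size alone (camera with TMM, adjusted p = 0.57). Without vehicle replicate 3, 4 rose and 5 fell. Of 13 mitochondrial genes, 8 rose, MT-ND3 fell and 4 did not pass, while 0 rose and 5 fell with scaling by library size alone (camera with TMM, adjusted p = 0.14). MT-ND5 had a log2 change of 0.20 with TMM and of -0.000817 with library size alone. The MT-ND3 call (edgeR, adjusted p = 0.040) was lost with DESeq2 with or without the count filter, without vehicle replicate 2 (0.170) or 3 (0.111) and without cytokine replicate 3 (0.106), and its adjusted p ranged from 1.5e-06 to 0.170 over 13 alternatives.

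Genes near type 1 diabetes loci rose in 11, fell in 4 and did not pass in 2 of 17 (camera, adjusted p = 0.0034), a call lost with an estimated correlation (camera, adjusted p = 0.090). SOCS1, an inhibitor of cytokine signalling, went from 0.248 to 30.8 CPM and the RNA sensor IFIH1 from 14.3 to 149 CPM. Islet progenitor and dedifferentiation genes rose in 7, fell in 1 and did not pass in 4 of 12, and rose in 4 and fell in 2 with scaling by library size alone (camera with TMM, adjusted p = 0.061). The list passed without vehicle replicate 2 (camera, adjusted p = 0.0477) and without cytokine replicate 2 (0.0449). Over 13 alternatives the adjusted p ranged from 0.00061 with fry, which does not compare a list with other genes, to 0.291 with camera and an estimated correlation. SOX11 rose 2.58-fold and SLC16A1 fell by 0.45 on the log2 scale. The SLC16A1 call was lost with DESeq2 and its own filter (adjusted p = 0.0661, the highest of 13 alternatives, which began at 1.2e-05). Of 16 reference genes, 7 rose, 4 fell and 5 did not pass, and 5 rose and 9 fell with scaling by library size alone (camera with TMM, adjusted p = 0.54). B2M was among those that rose and TFRC fell by 0.56 on the log2 scale.

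Alpha-cell markers rose in 2, fell in 4 and did not pass in 5 of 11 (camera, adjusted p = 0.57), with GC at 148 and 625 CPM and PLCE1 at 10.2 and 4.13 CPM, and fry gave the upward direction against a median of -0.051. Delta, gamma and epsilon-cell markers fell in 2 and did not pass in 4 of 6 (camera, adjusted p = 0.47). Ductal and acinar markers fell in 1 and did not pass in 4 of 5 (camera, adjusted p = 0.58), with KRT19 at 161 and 135 CPM in vehicle and cytokine libraries. The acinar gene CPA1 had 5.59 and 5.22 CPM, and passed as lower with scaling by library size alone (edgeR, adjusted p = 0.0444, range 0.0444 to 0.852 over 13 alternatives). Of 4 tested fibroblast and stellate markers, 3 rose and THY1 fell, with PDGFRB at 2.93 and 12.1 CPM. ACTA2, at 0.914 and 9.36 CPM, overlaps FAS on the opposite strand and is uncertain. The THY1 call (edgeR, adjusted p = 0.020) was lost with DESeq2 with the count filter (0.116) and without it (0.204), without vehicle replicate 2 (0.244) and without cytokine replicate 3 (0.0686), in a range of 0.00035 to 0.244 over 13 alternatives. Of 2 tested leukocyte and endothelial markers, CD68 rose from 5.19 to 21.4 CPM and CD14 had 2.63 and 2.06 CPM, which passed as lower with scaling by library size alone (edgeR, adjusted p = 0.0268, range 0.0268 to 0.536 over 13 alternatives).

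**Figure D3:**
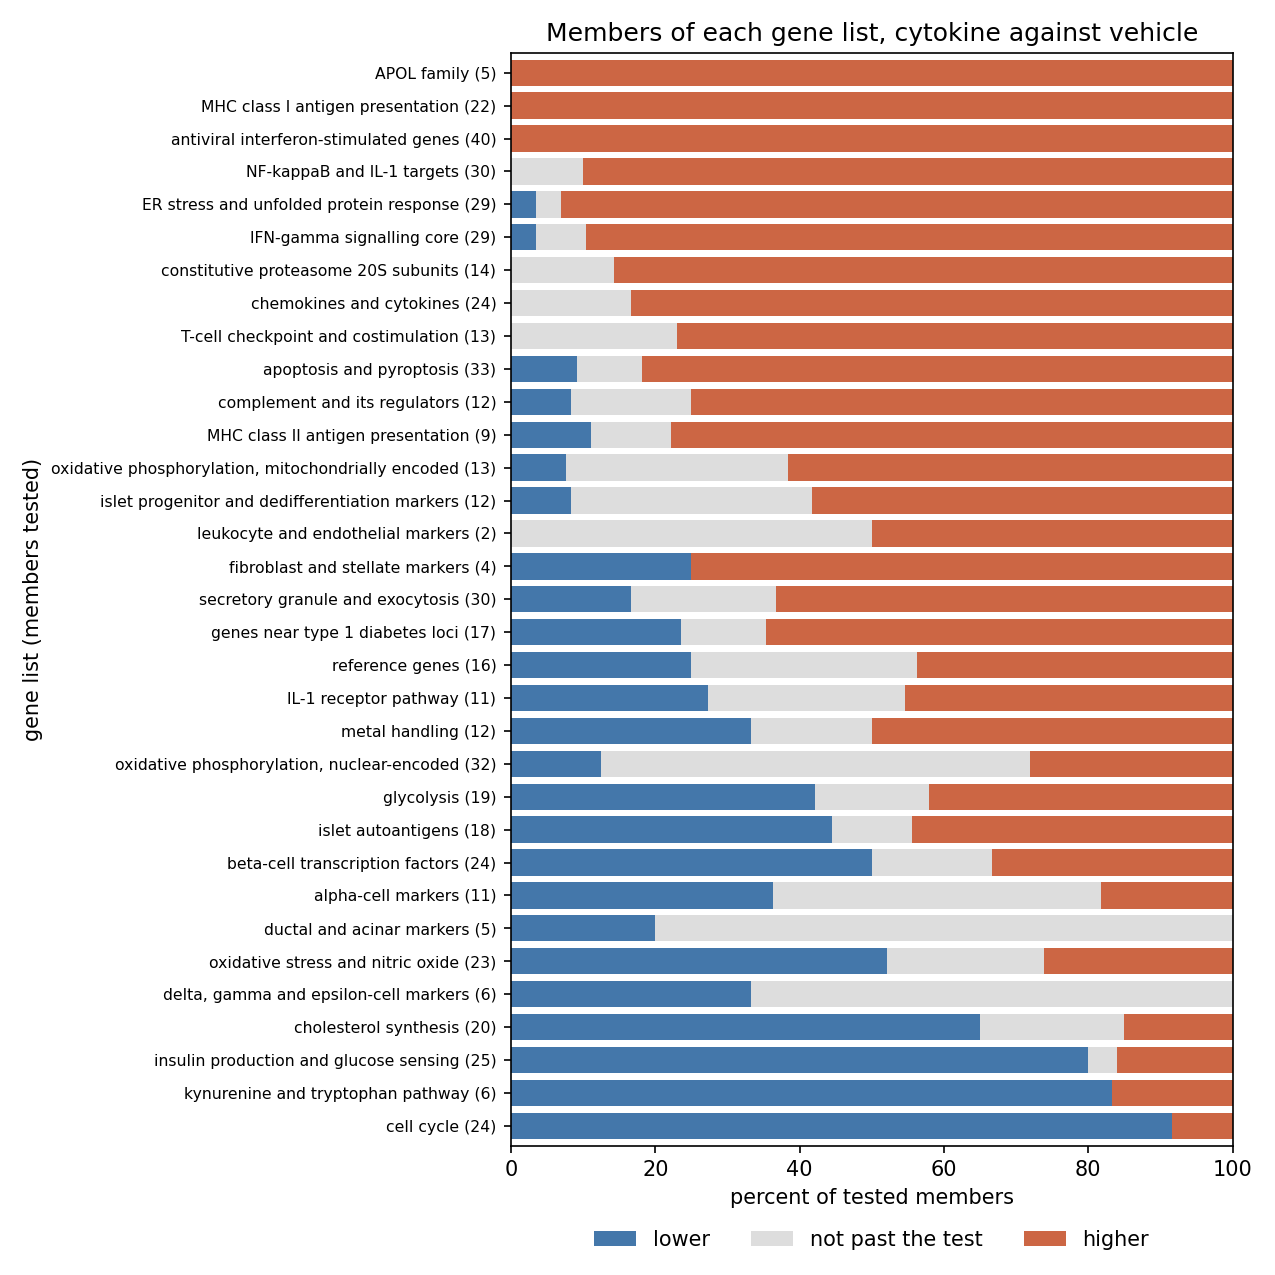
Percent of the tested members of each of 33 gene lists that were higher, lower or not past the edgeR test at an adjusted p of 0.05 with cytokines, with the number of tested members beside each list name. All members were higher in the APOL, MHC class I and antiviral lists, and 22 of 24 cell cycle genes were lower. With scaling by library size alone, more members were lower than higher in the lists for the interleukin 1 receptor pathway, metal handling, both oxidative phosphorylation lists and the reference genes, which have more higher members here.

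The 6 genes with the largest fall by the fixed rule were SYNDIG1L, LMO3, CSDC2, DUSP9, BCYRN1 and NHERF4. SYNDIG1L went from 12.7 ± 1.61 to 1.07 ± 0.264 CPM, a log2 change of -3.53 with SE 0.174 (edgeR, adjusted p = 2.7e-16). DUSP9, which encodes a phosphatase of MAP kinases, was 10.1-fold lower, and NHERF4 was 8.08-fold lower.

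Of 31 lists with a list test, 17 passed with camera's preset correlation, 14 upward and 3 downward, and 9 of these also passed with an estimated correlation. Adjusted over the list alone, member counts were equal in 29 of 33 lists. The others were the checkpoint list with 11 higher, the oxidative stress list with 13 lower, the nuclear oxidative phosphorylation list with 8 higher and the mitochondrial list with 9 higher. With scaling by library size alone, 3 members fell in the interferon gamma list, 2 in each of the MHC class II, 20S proteasome, NF-kappaB, ER stress and ductal and acinar lists, 1 in the checkpoint list, 4 in each of the complement and the delta, gamma and epsilon lists, and 7 in the alpha-cell list.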

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

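The alternatives were planned, except for counting INS with INS-IGF2 and DESeq2 with the count filter, which were chosen after the data were seen. Scaling by library size alone, which does not correct for the share of counts taken by induced genes, gave 2980 genes higher, 8791 lower and 1245 lower at least 2-fold, and log2 changes of -0.087 for NKX6-1 and -0.000817 for MT-ND5. DESeq2 without the count filter called 3365 genes lower, and 3820 with it. The other counts of called genes stayed within 1.5-fold of those reported, and of the 1830 genes called at 2-fold, 1681 to 1830 were still called with the same sign under the 13 alternative fits. An adjusted p of 0.01 left 4355 higher and 4114 lower genes.

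With an estimated correlation, camera adjusted p was 0.150 for MHC class II, 0.204 for the 20S proteasome, 0.0505 for complement, 0.105 for secretory granules, 0.204 for ER stress, 0.150 for cholesterol synthesis, 0.115 for the cell cycle and 0.0898 for type 1 diabetes loci. With no low-count filter, beta-cell transcription factors reached a camera adjusted p of 0.0330. Fry, which does not compare a list with other genes, gave adjusted p of 0.000273 for the interleukin 1 receptor pathway, 0.00170 for beta-cell transcription factors, 0.000605 for autoantigens, 0.00190 for mitochondrial oxidative phosphorylation, 0.000613 for progenitor markers and 0.000515 for reference genes. Fry turned the kynurenine list upward (adjusted p = 4.89e-05) and the alpha-cell list upward (adjusted p = 0.0489). Leaving out 1 library at a time, camera adjusted p ranged from 0.0435 to 0.0821 for cholesterol synthesis and from 0.0449 to 0.111 for progenitor markers. The cause of these changed calls was not tested.

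Deviations of libraries with the same replicate number correlated at 0.0902, 0.0744 and -0.161 over 9760 genes. Those of libraries with different numbers correlated at -0.180 to 0.147. No reference distribution was computed, so this check does not show whether libraries with the same number shared a batch. With the number as a block, 5001 genes were higher and 5097 lower, cholesterol synthesis had a camera adjusted p of 0.0689, and no other list call changed. Depth limits values near 1 CPM, and NOS2 lay below the filter.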

Other observations

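The genes and the region test in the first 2 paragraphs were chosen after the values were seen, as were the tests of nearness to raised genes, on genes beyond a start or on the other strand, on wrong-strand reads, on ribosomal protein genes with few pseudogenes and on fibroblast transcripts. Genes outside the fixed lists rose as well. The mRNA of LAP3, an aminopeptidase, went from 28.7 to 896 CPM, and UBE2L6, a conjugating enzyme for ISG15, from 3.83 ± 0.846 to 372 ± 5.16 CPM (SD, n = 3). The butyrophilin genes BTN3A1, BTN3A2 and BTN3A3 reached 233, 193 and 109 CPM from 25.5, 10.7 and 11.9 CPM. NAMPT, an enzyme of NAD synthesis, went from 42.8 to 346 CPM, C2CD4A from 13.9 to 145 CPM and C2CD4B from 6.75 to 55.7 CPM.

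HADH, a mitochondrial enzyme of fatty acid oxidation, fell by 1.46 on the log2 scale from 581 ± 16.2 to 210 ± 3.05 CPM (SD, n = 3). The receptor tyrosine kinase gene RET went from 39.1 to 9.36 CPM, and the nicotinic receptor subunit genes CHRNA3 and CHRNB4 from 31.5 to 6.18 CPM and from 16.9 to 2.51 CPM. On chromosome 6 from 28 to 34 Mb, 25 of 137 tested protein-coding genes were higher at least 2-fold, against 814 of 13902 elsewhere (Fisher exact test, two-sided, p = 4.87e-07). That region holds HLA genes, which share reads.

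For 5061 genes higher, 5140 lower, 1065 higher at least 2-fold and 765 lower at least 2-fold, 1 of 10 splits of the 6 libraries gave as many, the real split itself, and the highest of the other splits was 0 for each. With 10 splits, a share under 0.05 was out of reach.

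Of 46 genes that are not protein-coding and rose at least 8-fold, 19 overlapped or lay within 20 kb of 1 of 197 protein-coding genes raised as much, or 41.3% against 1.26% of all 3569 tested (Fisher exact test, two-sided, p = 3.40e-26). Of the 19, 5 overlapped such a gene on its own strand, as MIR6891 did HLA-B. Whether their counts were reads of the raised gene was not tested. Transcription running past the gene end may account for the 3 that lay downstream on the same strand, since 70% of downstream and 33.3% of upstream neighbours rose at least 2-fold, but with 10 and 3 genes these cannot be told apart (Fisher exact test, one-sided, p = 0.315). The positions of BISPR, MIR7703 and RIPK2-DT argue against transcription past the end of a gene raised at least 8-fold within 20 kb. These 3 lay beyond the start of each such gene near them, where transcription past its end does not run on either strand. Genes raised less or lying further away were not tested as sources, and 2 of the 3 lay on top of another gene higher at least 2-fold. The explanation stays open for 8 on the other strand, since the counting strand was not stated. Wrong-strand reads were taken to leave antisense genes at a nearly fixed share of the sense count. That share also depends on how far the 2 genes of a pair overlap, which was not measured. Over the 7 of 14 pairs whose antisense gene rose at least 8-fold, the 90th percentile of that share was 21290 times the 10th. That ratio rests on MMP25-AS1 and CYLD-AS1, at 2614% and 277% of sense genes with only 5.27 and 3.07 CPM. The others lay between 0.0170% and 5.70%, among them PSMB8-AS1, which also overlaps PSMB9 on its own strand. Since overlap was not measured, the spread cannot decide whether wrong-strand reads were the source. MMP25-AS1 and CYLD-AS1 had counts above those of their sense genes. Only there do the values argue against wrong-strand reads of the sense gene as the whole source. Wrong-strand reads stay open for the others, among them the antisense gene of WARS1 at 0.0170% of the WARS1 count.

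Of 82 ribosomal protein genes, which can share reads with pseudogenes, 66 were lower, 1 was higher and 15 did not pass the edgeR test, with a median log2 change of -0.32, and RPL3 went from 2081 to 1101 CPM. Matched genes argue against a general fall of short, abundant transcripts, since 95% of 10000 lists matched on exon length and level had medians from 0.0743 to 0.258. The length was that of all annotated exons, the level was the mean of both groups, and the closeness of the matches was not measured. Genes that rose could thus enter the lists through their cytokine level, so such a fall was not excluded. Reads shared with pseudogenes may contribute and stay open. The 4 genes with counts within 0.005 of whole numbers had a median of -0.15, and the 8 genes with at most 2 named pseudogenes a median of -0.19 with bounds of -0.41 and 0.13, too few genes to decide.

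The marker PDGFRB rose from 2.93 to 12.1 ± 0.825 CPM (SD, n = 3), and ACTA2 to 9.36 CPM, a value that is uncertain because FAS overlaps it on the opposite strand. Collagen transcripts gave little sign of fibroblast-like cells as a possible source, since COL1A1 had 0.615 ± 0.205 CPM (SD, n = 3) and SPARC 0 CPM in the cytokine libraries. How cytokines change these transcripts in such cells was not measured, so that source was not excluded. COL1A1 lay below the count filter and had 0.189 ± 0.206 CPM (SD, n = 3) in the vehicle libraries, while VIM rose from 0.482 to 2.21 CPM and FN1 from 2.97 to 73.0 CPM. A change within the beta cells remains a hypothesis that was not tested separately.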
